A study of Mus musculus with 2 samples.

How the data were processed

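Gene expression was measured in mouse hematopoietic stem cells (HSC, the rare bone marrow cells that give rise to all blood lineages) on 2 Affymetrix 3' expression arrays. One array held RNA of cells labelled Sirt6 knockout and the other RNA of cells labelled wild type, both from mice aged 3 months. Each genotype therefore had 1 array. Total RNA was extracted with Trizol and labelled with biotin, per the labels, although the labelling protocol names another label. How the cells were sorted, how many animals were pooled and how the Sirt6 allele was disrupted are not given in the sources used here.

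The deposited values are linear signal intensities, 1 per probe set and array, and MAS5 is named as the tool per the submitters' processing notes. MAS5 summarises the perfect-match and mismatch probes of a probe set on each array separately and then scales the array. The scaling target, the software version and the present or absent calls are not given in the sources used here. The table held 45037 probe sets. The median signal was 60.7 on the array labelled knockout and 60.8 on the wild-type array, and the trimmed means (without the lowest and highest 2%) were 217 and 218. The arrays were therefore already on a common scale and were used as deposited on the log2 scale. No control (AFFX) probe sets were among the rows used here, so the planned comparison of 3' and 5' control signals as a sign of RNA quality was not analysed here.

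Probe sets were named from the platform annotation. Of the 45037 probe sets, 34945 named 1 gene, 932 named several genes and 9160 had no gene named. Only those with 1 gene were given a gene name. Of the 34945, 34741 matched a RefSeq gene record (GRCm38.p6) through the Entrez identifier, which changed 0 symbols. A gene was represented by the probe set with the highest mean log2 signal over both arrays. A floor was set at the median over all probe sets of the mean log2 signal (a signal of 60.5, or 5.92 on the log2 scale), the same for both arrays, because MAS5 values of dim probe sets are dominated by noise. A gene counted as measured when above the floor on at least 1 array, and a value under the floor was raised to it. A ratio against a value under the floor is a lower bound and is written as "at least". Of 18193 named genes, 11547 were measured, 10831 of them above the floor on both arrays, 433 only on the array labelled knockout and 283 only on the wild-type array.

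With 1 array per group there is no replicate, so no test between genotypes, SD or p-value was computed. The number of arrays limits the precision, and any difference given here compares these 2 RNA samples. Genes were counted as higher or lower by a fixed size, 2-fold for all genes and 1.5-fold for list members. As a measure of technical error only, the SD of the log2 ratio between probe sets of the same gene was computed on the 4632 genes with at least 2 probe sets above the floor on both arrays. Fixed gene lists (34 in all, 23 pathways or gene groups and 11 sets of cell type markers) were described by their median log2 ratio. Its percentile was taken among medians of 10000 random lists of the same size, matched on mean signal in 20 bins. A list was said to stand apart below percentile 2.5 or above percentile 97.5, so that 5% of lists of randomly drawn genes would do so by chance. Lists with fewer than 5 measured genes were not ranked. The percentile describes these 2 arrays and is not a test of the genotype.

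The lists, the floor, the thresholds, the alternatives and the rule for named genes were written before the data were examined. The rule named Sirt6, and the 12 genes highest and 12 lowest in ratio among genes with at least 2 probe sets above the floor on both arrays that all pointed the same way. It also named the 5 genes with the largest bound in each direction, and the 4 members of each list with the largest ratio. Sex-linked and hemoglobin genes were all named. Genes named outside this rule are marked as such.

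Alternatives were quantile normalization, centring of each array on its median, loess on mean signal (span 0.3, statsmodels 0.14.6), floors at percentiles 25 and 75, no floor, a pseudocount of 1 floor, the median over a gene's probe sets, leaving out probe sets ending in _x_at or _s_at (which can match related transcripts), and sizes of 1.5-fold and 4-fold. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The procedure was tested on simulated data made from the mean signals of these arrays, with noise of SD 0.22 on the log2 scale over 11359 measured genes. Of 107 genes given a log2 change of 1.5, 94.4% came out at least 2-fold changed in the right direction, against 1.08% of 93 genes given a log2 change of 0.5 and 1 of 11139 unchanged genes. A list of 20 genes shifted by 0.3 ranked at percentile 100, and 4% of 200 unchanged lists stood apart. The noise had the size of the SD between probe sets of the same gene, so it held no error between animals or RNA samples. Unchanged lists matched the random lists by construction, so their share says nothing about lists of genes expressed together. The simulated values are therefore not error rates for the comparison of the real arrays. The recovery of the larger changes fell short of the bar first set for this test, which was lowered after the value was seen, and the number of unchanged lists was reduced to save time.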

Results

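Expression profiles of mouse HSC of both genotypes were compared to ask how transcript levels differ when Sirt6, a nuclear NAD-dependent deacylase of histones, is knocked out. The data were 1 array of cells labelled knockout and 1 array of wild-type cells. The log2 signals of the 2 arrays correlated with Pearson's r = 0.98 across all 45037 probe sets, which are not independent replicates. Of the probe sets, 50.1% lay above the floor on either array. The median log2 ratio of the 11547 measured genes was 0.0023, so ratios are given relative to a centre near 0. The SD of the log2 ratio between probe sets of the same gene was 0.22, and the probe sets of 2426 of 4632 genes (52.4%) all pointed in the same direction. With 1 array per genotype, none of the differences below carries a biological error.

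The targeted gene was not lower on the array labelled knockout. The single Sirt6 probe set read 174 on that array and 124 on the wild-type array, a ratio of 1.40 (log2 0.49). Among probe sets of similar brightness (log2 signal 7 to 8), this ratio lay at percentile 96.9. Which part of the transcript the probe set covers relative to a deleted part is not given in the sources used here, so the signal does not check the genotype. The array is called "the array labelled knockout" throughout, and every direction below rests on that label. The list of sirtuins and NAD enzymes, which includes Sirt6, did not stand apart, with 0 of 15 measured genes at least 1.5-fold different and a median of -0.09 (percentile 9.12). Naprt, an enzyme of NAD synthesis from nicotinic acid, had a log2 ratio of -0.50, Sirt5 of -0.38 (-0.02 on its other measured probe set) and Sirt7 of -0.17.

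Among all measured genes, 46 were at least 2-fold higher and 66 at least 2-fold lower on the array labelled knockout, together 0.97% of 11547. Of these, 5 of the higher and 15 of the lower genes were bounds against the floor. Among genes with at least 2 probe sets above the floor on both arrays, 3 of 5 higher and 15 of 17 lower genes had all probe sets pointing the same way. At a size of 1.5-fold the counts were 198 higher and 304 lower. These counts depend on the floor: with the floor at percentile 75 they were 14 and 17, and with no floor 182 and 189.

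Among genes whose probe sets pointed the same way, the largest differences were toward lower signal on the array labelled knockout. Ighm, the IgM heavy chain, read 707 against 3684 in wild type (log2 -2.38), although its 8 measured probe sets ranged from -2.38 to -0.04. The imprinted noncoding RNA Meg3 read 248 against 1098 (log2 -2.15), while its 8 measured probe sets ranged from -2.15 to 0.06. Tgm2, a transglutaminase, was lower on its 4 measured probe sets, with log2 ratios from -2.19 to -1.81. Ndn, an imprinted growth suppressor, read 161 against 482 (log2 -1.58). The transcription factor Hlf read 795 against 1742 (log2 -1.13), with its second probe set at -0.63. Mllt3, a chromatin reader expressed in HSC, read 108 against 242 (log2 -1.17). Crispld1 (log2 -1.20), Ttc4 (-1.18) and Csgalnact1 (-1.11), a chondroitin sulfate synthesis enzyme, were also lower on both of their probe sets. Tmem215 (-2.01), Mpp5 (-1.91) and the repressor Rest (-1.39) met the rule by direction only: another probe set of each gave -0.21, -0.44 and -0.0022. The largest bounds among genes under the floor on the array labelled knockout were those of Cxcl12, a chemokine that retains HSC in marrow (at least 7.63-fold lower), Fstl1 (at least 3.30-fold), Fhl1 (at least 2.98-fold), Gas6, a ligand of TAM receptors (at least 2.61-fold), and Plpp3 (at least 2.55-fold).

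Differences toward higher signal on that array were smaller among such genes. Ccl9, a chemokine of myeloid cells, read 2375 against 909 (log2 1.38), and its second probe set gave 1.37. Gsr, glutathione reductase, was higher by log2 0.99, the lamin gene Lmnb1 by 0.84, Rgcc by 0.83 and Csf2rb, the shared beta chain of the GM-CSF, IL-3 and IL-5 receptors, by 0.81. Pdgfrb (0.92), Cd244a (0.83), a surface receptor used to tell multipotent progenitors from HSC, and the C-type lectin Clec4e (0.81) were also higher on both of their probe sets. Mvd, of sterol synthesis (0.89), and Lpcat2 (0.86) were higher, with second probe sets at 0.44 and 0.19. The probe sets of Zc3h7b read 1.32 and 0.17, and the 5 measured ones of Wipi1 from 1.14 down to 0.06. Among genes under the floor in wild type, Ly6k was at least 3.08-fold higher, Pi16 at least 2.29-fold, Trnp1 at least 2.12-fold, Pmaip1, a p53-induced BH3-only gene, at least 2.09-fold, and Trbv1 at least 2.07-fold.

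HSC markers and regulators were lower as a group on the array labelled knockout. Of 32 measured genes, 15 were at least 1.5-fold lower, 0 were at least 1.5-fold higher and 17 lay between, and 25 had a negative ratio. The 15 include Runx1 and Prdm16, named after the values were seen, whose probe sets did not all point the same way. Not every marker was lower: the 17 between include Slamf1 (log2 -0.10), Kit (0.03), Cd34 (0.15) and Gfi1 (0.34). These were also named after the values were seen. The median log2 ratio of the list was -0.42, below all 10000 random lists (percentile 0), whose central 95% ran from -0.07 to 0.08. Besides Ndn, Mllt3 and Hlf, the largest differences were in Fhl1 (at least 2.98-fold lower) and Fgd5, a guanine exchange factor that marks HSC (88.5 against 230 signal units, log2 -1.38). With the floor at percentile 75, which left 23 genes, the median was -0.12 (percentile 0.03). The imprinted gene list overlapped it in 2 genes (Cdkn1c and Ndn) and had a median of -0.82 (percentile 0), with 5 of 9 measured genes at least 1.5-fold lower. These were Meg3, Ndn, Grb10 (log2 -1.52), Phlda2 (at least 2.13-fold lower) and Cdkn1c, the p57 cell cycle inhibitor (log2 -0.82). Without the shared genes the median of the other 7 was -0.15, and without a floor that of 16 imprinted genes was -0.03 (percentile 14.4).

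**Figure D1:**
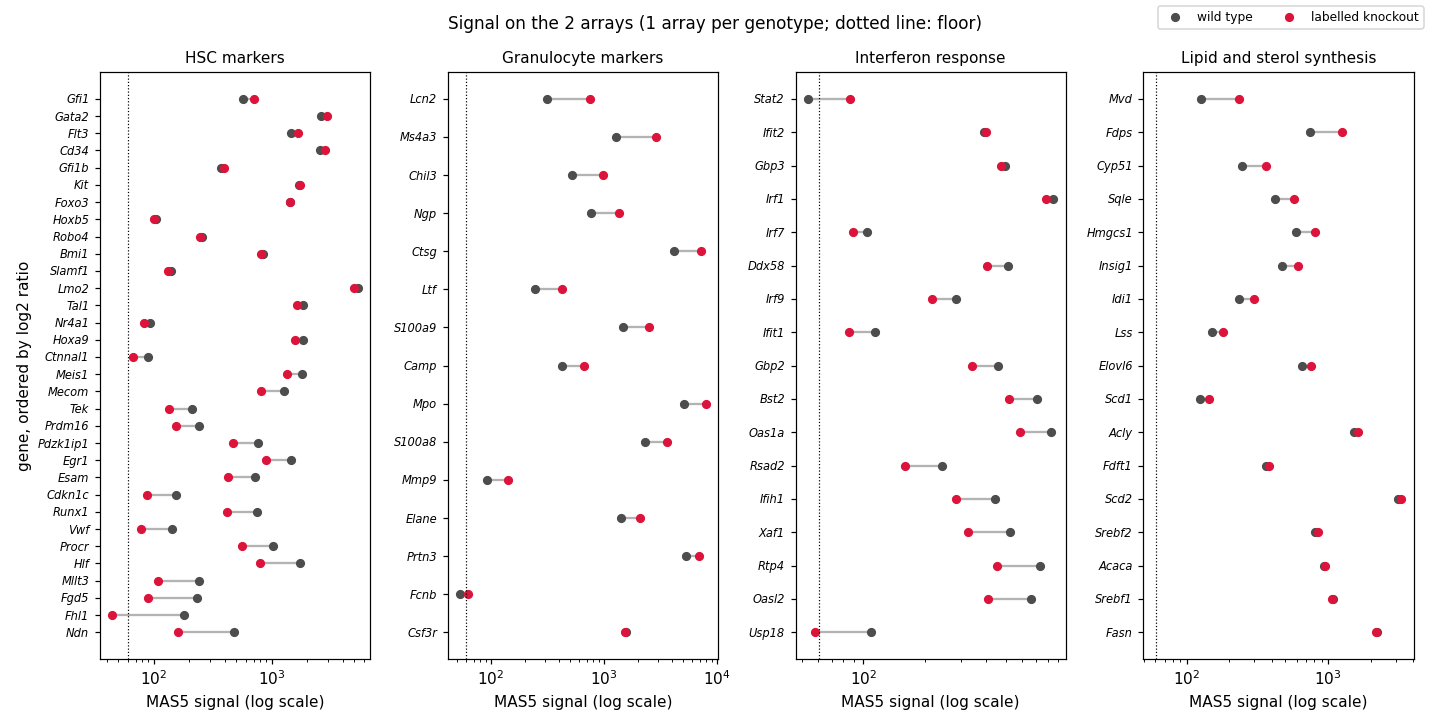
MAS5 signal (log axis) of each measured gene of 4 lists on the array labelled knockout (red) and the wild-type array (grey), 1 array each; the dotted line is the floor of 60.5 and genes are ordered by log2 ratio. Of the HSC markers 25 of 32 lie to the left of wild type, and of the granulocyte markers 14 of 15 lie to the right.

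Markers of several other blood cell types differed between the same arrays. Granulocyte markers were higher on the array labelled knockout: 11 of 15 measured genes were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 0.65 (percentile 100). Lcn2 read 751 against 314 (log2 1.26), Ms4a3, a marker of granulocyte-monocyte progenitors, 2887 against 1286 (1.17), Chil3 988 against 517 (0.93) and Ngp 1359 against 759 (0.84). Basophil and mast cell markers had a median of 0.37 (percentile 99.98), with 3 of 9 genes at least 1.5-fold higher: Fcer1a (log2 1.18), the basophil protease Mcpt8 (1.14) and Hdc, histidine decarboxylase (0.71). Cma1 was lower (-0.89). The eosinophil list had 2 measured genes, Siglecf (1.14) and Prg2 (0.81), and was not ranked. Monocyte and macrophage markers as a list did not stand apart (median -0.07, percentile 13.1, with 6 positive and 7 negative ratios), although F13a1 read 1273 against 428 (1.57). Its other leading members were Itgam (0.46), the receptor gene Csf1r (0.45, with its other probe sets at 0.69 and 0.76) and C1qc (-0.38).

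Lymphoid genes went both ways. The B cell list had a median of 0.50 (percentile 100), with 4 of 11 measured genes at least 1.5-fold higher and 1 lower. Vpreb1 and Igll1, which encode the surrogate light chain of B cell precursors, read 433 against 127 (log2 1.78) and 296 against 96.2 (1.62), and the adaptor Blnk was higher by 0.87. Ighm was the lower one. With the floor at percentile 75, which left 5 genes, the B cell median was 0.11 and no longer stood apart. Of 18 T and NK cell genes listed, 7 were measured. The T cell genes Cd3d, Cd3e, Cd3g and Cd4, named here after the values were seen, were under the floor on both arrays. The T and NK cell list had a median of 0.22 at percentile 97.54, just past the limit, led by Thy1 (0.90), Gzmb (0.85), Il7r (0.53) and Cd8a (0.22). Its median lay inside the random range under loess, with the floor at percentile 25, with no floor and after a correction for genomic span chosen after seeing the data. The lymphoid-primed progenitor list had a median of 0.04 (percentile 69.3). Rag1, a recombinase subunit, was at least 1.81-fold higher, and Notch1 had a ratio of -0.30.

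Dendritic cell markers had a median of -0.38 (percentile 0), with 3 of 9 measured genes at least 1.5-fold lower, all of the MHC class II pathway. Siglech, Ciita, Xcr1 and Ccr7 of the same list were under the floor on both arrays. Its measured members Bst2 and Flt3 also belong to the interferon and HSC lists. These unmeasured and shared genes were named after the values were seen. H2-Eb1 read 125 against 270 (log2 -1.12), H2-Aa 322 against 670 (-1.06, on 3 measured probe sets from -1.06 to -0.88) and the invariant chain Cd74 312 against 547 (-0.81), while Irf8 was higher by 0.46. With the floor at percentile 25 the median was -0.02 (percentile 22.6). Endothelial and stromal markers had a median of -0.77 (percentile 0), with 4 of 7 measured genes at least 1.5-fold lower and 2 higher. Cdh5, Col1a1, Col3a1, Lepr, Adipoq, Kitl and Dcn of that list were under the floor on both arrays. They were named after the values were seen, and the median covers none of them. Among the lower ones were Cxcl12, Emcn, the endomucin gene (62.5 against 176, log2 -1.50), and the matrix gene Sparc (-0.86). The higher ones were Pdgfrb (0.92) and Pecam1 (0.69), the latter named after its value was seen. Without a floor that list's median was -0.10 (percentile 5.28).

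Erythroid and megakaryocyte markers were mixed and did not stand apart, with medians of -0.12 (percentile 4.62) and 0.09 (percentile 87.0). Car1, a carbonic anhydrase, read 128 against 499 (log2 -1.96) and the water channel Aqp1 89.98 against 178 (-0.98), while the transferrin receptor Tfrc read 2608 against 1595 (0.71) and Sptb was higher by 0.71. Itga2b, CD41, was higher (0.88), and Vwf (-0.87), Pf4 (-0.76) and Rab27b (-0.59) were lower. The 1 measured hemoglobin gene, Hba-a2, was near the floor on both arrays (69.1 against 75.1).

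Interferon response genes were lower. Of 17 measured, 6 were at least 1.5-fold lower and 0 higher, 15 had a negative ratio, and the median was -0.42 (percentile 0). Usp18 was at least 1.80-fold lower, and Oasl2 and Rtp4 each had a log2 ratio of -0.70. Xaf1 read -0.69 on its brightest probe set and 0.46 on its second. Genes of lipid and sterol synthesis were higher as a group, with 15 of 17 positive ratios, 2 at least 1.5-fold higher and a median of 0.22 (percentile 100). The largest differences were in Mvd (0.89) and Fdps (0.76), of the mevalonate pathway, and in the cholesterol synthesis genes Cyp51 (0.58) and Sqle (0.45). DNA damage repair genes had a small negative median of -0.14 (percentile 0.05), with 20 of 26 negative ratios and 0 genes at least 1.5-fold different. Trp53bp1 (-0.41), Chek1 (-0.29), Xrcc4 (-0.27) and Xrcc6 (-0.21) led that list. After centring each array on its median it was -0.08 (percentile 0.07).

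**Figure D2:**
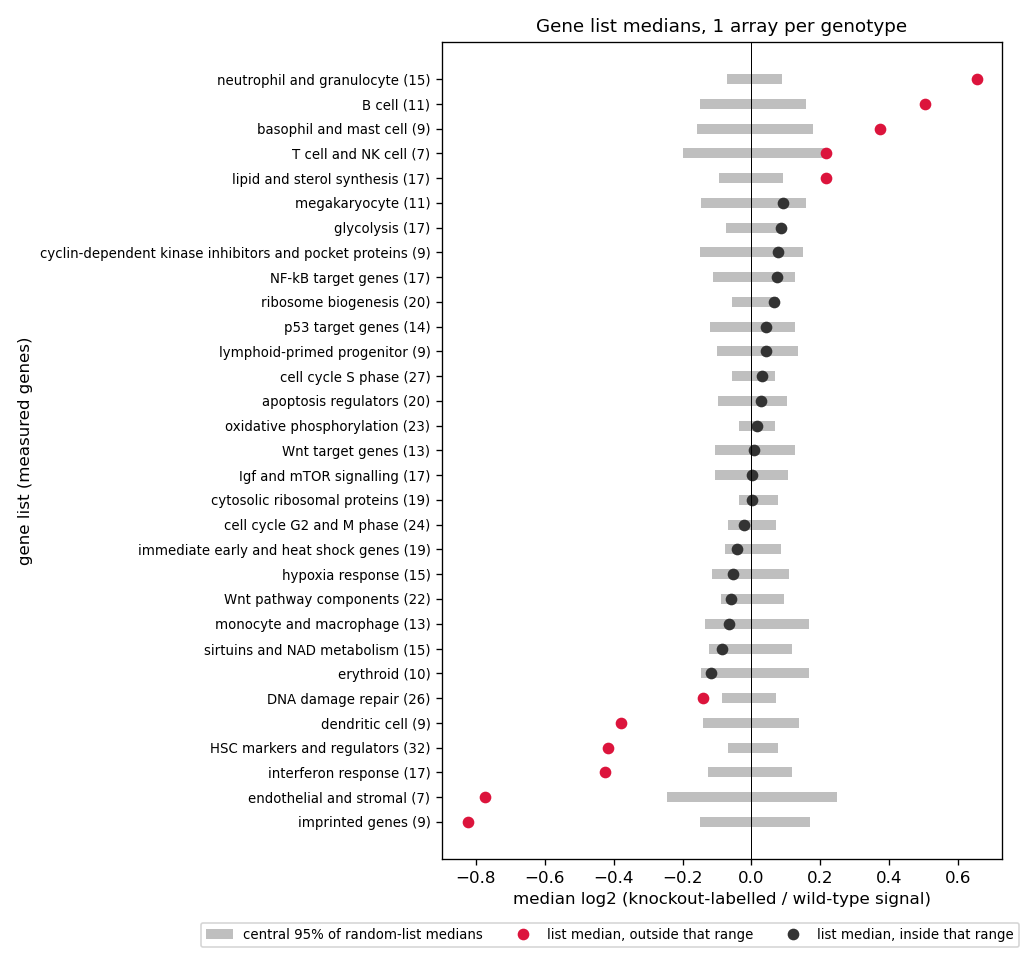
Median log2 ratio of the array labelled knockout over wild type for the 31 ranked gene lists (points; measured genes in parentheses), with the central 95% of medians of 10000 matched random lists (grey bars). The granulocyte list (0.65) lies highest and the imprinted gene list (-0.82) lowest.

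Wnt signalling and the cell cycle did not stand apart. Of 13 measured Wnt target genes 0 were at least 1.5-fold different, and the median was 0.0069 (percentile 51.1). Ccnd1, cyclin D1, read 331 against 454 (log2 -0.46), Myc 1656 against 1319 (0.33), Bambi 0.32 and Notum 0.25. Axin2 and Lef1, which are often used as Wnt readouts, were under the floor on both arrays and were named here after the values were seen. Wnt pathway components had a median of -0.06 (percentile 8.38), with Fzd3 at least 1.47-fold lower, Fzd7 at -0.50, Bcl9 at -0.25 and Fzd6 at -0.24. When probe sets ending in _x_at or _s_at were left out that median was -0.09 (percentile 1.70). Genes of S phase (27 measured, median 0.03, percentile 78.8) and of G2 and M phase (24 measured, median -0.02, percentile 24.3) included 1 gene at least 1.5-fold different, Tyms (-0.62). Ccne1 (0.48), Rrm2 (0.22) and Rfc3 (-0.19) in S phase and Plk1 (0.31), Cdc25c (-0.26), Cdc20 (0.25) and Cenpe (0.23) in G2 and M phase followed. Cell cycle inhibitors went both ways (median 0.08, percentile 84.6): Cdkn1c was lower (-0.82), Cdkn1a higher (350 against 229, 0.61), Cdkn2c -0.31 and Cdkn2b at least 1.20-fold higher.

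Glycolysis genes had a median of 0.09 (percentile 97.1), just inside the random range, with 13 of 17 positive ratios and 0 genes at least 1.5-fold different. Slc16a3 (0.52), Pkm (0.41), Pfkp (0.41) and Pfkl (0.35) led the list, which stood apart at a median of 0.19 when _x_at and _s_at probe sets were left out. Hypoxia response genes had a median of -0.05 (percentile 19.1), with Egln3 (0.74), Ero1a (0.58), Mxi1 (0.38) and Bhlhe40 (-0.45). Oxidative phosphorylation (median 0.02, percentile 54.4) and cytosolic ribosomal protein genes (median 0.00042, percentile 27.2) included 0 genes at least 1.5-fold different, with Uqcrc1 (0.14), Uqcrfs1 (0.14), Ndufa1 (0.13) and Cox5a (0.13), and Rpl37 (0.15), Rpl14 (-0.14), Rpl4 (0.10) and Rps6 (-0.10), as their leading members. Ribosome biogenesis genes had 17 of 20 positive ratios and a median of 0.07 (percentile 95.5), led by Utp20 (0.31), Bop1 (0.29), Wdr12 (0.24) and Wdr43 (0.18).

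The remaining lists did not stand apart. They were p53 targets (median 0.04, percentile 73.4), apoptosis regulators (0.03, percentile 70.5), NF-kB targets (0.07, percentile 86.2), Igf and mTOR signalling (0.0024, percentile 51.3) and immediate early and heat shock genes (-0.04, percentile 12.4). Within them, Pmaip1 and Cdkn1a were higher, and Zmat3 (-0.56), Gadd45a (0.28), Apaf1 (0.48), Bik (0.47) and Bak1 (0.40) stayed under 1.5-fold. Ccl3 read 126 against 219 (log2 -0.79), while Il1b (0.57), Tnf (0.29) and Birc3 (0.28) were under 1.5-fold. Igf2r was at least 1.93-fold lower, with Tsc1 at -0.46, Rptor at 0.29 and Foxo1 at -0.28. Egr1 read 887 against 1464 (-0.72), followed by Fos (-0.46), Hsph1 (-0.40) and Dusp1 (-0.39). Of the 31 ranked lists, 11 stood apart, 5 higher and 6 lower, against 1.55 by chance if list members behaved like randomly drawn genes, which genes expressed together do not. In 9 lists whose medians lay inside the random range the mean had the opposite sign of the median, as in monocyte markers (mean 0.17). Among the list members named above, a further measured probe set pointed the other way for Wdr12 (-0.38), Cdc25c (0.25), Sparc (0.25), Mxi1 (-0.20), Pfkl (-0.06), Rrm2 (-0.05), Foxo1 (0.05), Birc3 (-0.04) and Tsc1 (0.01).

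Sex-linked genes differed between the arrays and both arrays held signal of both kinds. The Y-linked genes Eif2s3y (316 against 645, log2 -1.03), Uty (78.0 against 144, -0.89) and Kdm5d (179 against 290, -0.70) were lower on the array labelled knockout. Xist, the RNA of the inactive X chromosome, read 5224 against 3365 on its brightest probe set (0.63). Its other probe sets disagreed, at 1.98 and -0.83.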

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

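Probe sets with no gene named were outside the comparisons of genes. The comparison of them with named probe sets was chosen after the values were seen. Of 3129 such probe sets above the floor on at least 1 array, 72 (2.30%) were at least 2-fold lower and 13 (0.415%) at least 2-fold higher on the array labelled knockout. Among 19881 probe sets with 1 gene named, 156 (0.785%) were lower and 60 (0.302%) higher by that size. No explanation was tested for this difference, and which transcripts these probe sets measure was not analysed here. Named and unnamed probe sets were not matched on signal. The spread of ratios depends on signal (SD 0.36 near the floor and 0.13 above a log2 signal of 11).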

How the results depend on the processing

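The alternatives were chosen before the data were examined, except the correction for genomic span, which was chosen after seeing the data. With 1 array per genotype no array could be left out, and the RNA quality comparison was not run. Sirt6 was higher on the array labelled knockout under all 8 alternatives that gave it a value. Its 1 probe set lay above the floor on both arrays. A lower floor, no floor, the median of probe sets and leaving out _x_at and _s_at probe sets therefore could not change its value. HSC, interferon, DNA repair, lipid and sterol, and granulocyte lists stood apart in the same direction under every alternative run, and the basophil list under every one but the floor at percentile 75, where it, the T and NK cell, erythroid, imprinted and endothelial lists had too few genes to rank. The HSC medians ran from -0.43 to -0.12 and those of granulocyte markers from 0.64 to 0.76. The counts of genes at least 2-fold higher and lower (46 and 66) were 14 and 17 with the floor at percentile 75, 182 and 189 with no floor, 20 and 26 with a pseudocount, 198 and 304 at 1.5-fold, and 1 and 6 at 4-fold. With the floor at percentile 25, 67 genes were higher and 121 lower (64.4% of these lower, against 58.9%). The share of genes whose probe sets all pointed the same way (52.4%) was 53.9% after median centring, 48.1% and 61.2% with floors at percentiles 25 and 75, and 44.3% with no floor. The T and NK cell list no longer stood apart under loess (0.22), the floor at percentile 25 (0.18), no floor (0.21) or the span correction (0.21), and its median was 0.37 without _x_at and _s_at probe sets. Dendritic cell markers no longer stood apart with the floor at percentile 25 (-0.024) or no floor (-0.045), and their median was -0.25 without those probe sets. Without a floor neither imprinted genes (-0.035) nor endothelial and stromal markers (-0.10) stood apart, while eosinophil markers (0.82) did and hemoglobin genes (0.17) did not, with 6 genes in each of these lists, which had too few measured genes to rank with the floor. With the floor at percentile 75 B cell markers no longer did (0.11), while monocyte markers did (0.19, 5 genes). Glycolysis stood apart with a pseudocount (0.083) and without _x_at and _s_at probe sets (0.19), as did Wnt components (-0.089) and ribosome biogenesis (0.085) in the latter. A pseudocount, which shrinks ratios of dim genes by construction, gave medians of -0.54 for imprinted genes, 0.28 for B cell markers and -0.50 for endothelial and stromal markers, which with the floor at percentile 25 had -0.20. Floors change which genes are measured, and otherwise the cause was not tested. Values of named genes under alternatives moved by more than the SD between probe sets in 102 instances and by less in 1188. The sign changed only for Wdr12, from 0.24 to -0.07 with the median of probe sets. Signal over background limits dim genes: the SD of probe set ratios was 0.36 near the floor and 0.13 above a log2 signal of 11.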

Other observations

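All tests below except that of array scaling were chosen after the results were seen, although the outcome expected of the correction for gene span was written down before its value was known. The genes in the next paragraph, and Sdc1, Jchain, Mzb1, Derl3, Xbp1, Cd79a, Cd79b, Cd22, Cd37 and Cr2, lie outside the rule for named genes and were chosen after values were seen.

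Single genes outside the fixed lists also differed, and no test of them as a group was made. Cebpa, a transcription factor of granulocyte-monocyte progenitors, read 412 against 176 in wild type (log2 1.23). Haptoglobin (Hp) was higher by log2 1.23, the lysosomal inhibitor gene Cst7 by 1.35, the receptor Trem3 by 1.19, the NADPH oxidase gene Cybb by 1.08 and the adaptor Tyrobp by 0.83. Fbp1, a gluconeogenic enzyme, read 940.0 against 247 (1.93), the metallothionein Mt1 1560 against 542 (1.53) and Clec2i 363 against 63.5 (2.52), the wild-type value being close to the floor. Among lower genes, Iglv1, an immunoglobulin light chain segment, read 355 against 2028 (-2.51), the proteoglycan Bgn 162 against 538 (-1.73) and the retinal dehydrogenase Aldh1a1 270.2 against 677 (-1.32).

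For the lower HSC list and the higher granulocyte list, array scaling was tested on the HSC list only. Its median was no nearer 0 than -0.36 under quantile, centred and loess scaling. This argued against a shift shared by all genes or by genes of similar signal. That the list stayed apart from random lists adds nothing, because random lists matched on signal shift along with it. A trend of lower signal with genomic span was argued against, because the median of the 577 longest genes was -0.0094 (95% bootstrap interval -0.037 to 0.017), while correction for span moved too little to test anything (HSC median -0.42). Even dilution of HSC by all other blood cells stays open: granulocyte and monocyte medians differed by 0.72 (interval over genes 0.29 to 0.93) and dendritic (-0.38) and erythroid (-0.12) medians were negative, but monocyte markers went both ways and stood apart as higher (0.19) with the floor at percentile 75, dendritic markers did not stand apart with the floor at percentile 25 (-0.024), and erythroid markers did not stand apart. A larger share of granulocyte progenitors may underlie the granulocyte median of 0.65 but cannot be told apart from a difference within HSC, since the sort is not given here. Swapped labels stay open too, because Sirt6 was higher (log2 0.49) on the array labelled knockout and its probe set's position is unknown, and a genotype effect stays untested with 1 array each.

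Ighm was lower while Vpreb1 and Igll1 were higher on the array labelled knockout. A single cross-hybridizing probe set was argued against, since 3 of 8 measured Ighm probe sets were at least 1.5-fold lower. The others ranged from -0.29 to -0.04, and cross-hybridization shared by several probe sets was not tested. Mature B or plasma cells on the wild-type array stay open: of a list of their genes, 7 of which the B cell or dendritic list also holds, 4 of 14 (28.6%) were at least 1.5-fold lower, namely Cd74, H2-Aa and H2-Eb1 of the MHC class II pathway and the plasma cell gene Sdc1 (log2 -0.999), while of other plasma cell genes Jchain read 1776 against 2462 (-0.47), Mzb1 -0.05, Derl3 0.08 and Xbp1 0.12. The light chain segment Iglv1, outside that list and also chosen after the values were seen, was lower as well (355 against 2028, log2 -2.51). The median of Cd79a, Cd79b, Cd22, Cd37 and Cr2 was 0.28, with 0 of 5 lower by more than the SD between probe sets. Cd79a, Cd22 and Cr2, however, lay under or near the floor in wild type. B cell precursors also express some of these 5 genes, so their median decides nothing. No sort that would remove such cells is given here, and a genotype effect stays open and untested.

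Pools with different shares of male and female mice may explain the lower Y-linked genes, whose median log2 ratio was -0.89 over 3 measured genes. Of 3 Xist probe sets 2 were higher on the array labelled knockout and the other was lower, which keeps this open. The median of 4 X-linked genes known to escape inactivation was 0.36. The labels give no sex.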
